A study of Mus musculus with 16 samples.

How the data were processed

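Gene expression was measured in mouse embryonic stem (ES) cells, pluripotent cells derived from the early embryo, of a 129/B6 hybrid background. Per the labels, clones 10 and 15 were compared with and without 4-hydroxytamoxifen (OHT), given at 800 nM for 24 hours to remove Rybp, a component of the Polycomb repressive complex PRC1. Cells given OHT are called KO here and untreated cells of the same clone are the control. RNA was taken at day 4 and day 12. The 16 arrays form 4 groups (control and KO at each day) of 4 arrays, each with 2 arrays of either clone, numbered replicate 1 and replicate 2. No control received OHT, so effects of OHT, or of a recombinase it activates, cannot be told apart from those of Rybp loss. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these arrays, which may be partly technical. Per the labels' protocols, cells grew in serum with leukaemia inhibitory factor on irradiated mouse fibroblast feeders or on gelatin, and no label says which array came from which.

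Total RNA was extracted with Trizol and copied into biotin-labelled cRNA, per the labels' protocols. The series' design text names the 430A 2.0 array, whereas the deposited table holds the 45101 probe sets of the larger Mouse Genome 430 2.0 array. The deposited values are intensity on a linear scale, 1 value per probe set and array, from 0.144 to 52570. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, with no version, order or setting stated. In the deposited table all 16 arrays hold the same set of values in different order, so they had been quantile-normalized together before deposit, with a median intensity of 93.3 on every array. Detection calls and scanner files were not used here. The fit had been planned for values already on a log2 scale, and since the deposited values are linear they were log2-transformed with no offset. The number of arrays limits the precision. The median SD between arrays of a clone and group was 1.19 on the log2 scale for genes with a mean below 5 and 0.19 for genes above 11, so large fold changes from dim controls carry large errors. For genes past the threshold whose printed fold this moved by more than 1.5 times, the fold with every value under the 25th percentile of intensity (28.3) raised to it is given as well.

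Probe sets were named through the platform annotation of the table. After 64 AFFX control probe sets were left out, 34945 probe sets had a single gene symbol, 932 had several and 9160 had none. Of the named probe sets 34741 matched a gene of the mouse annotation by Entrez identifier and 0 symbols needed updating. That annotation, assembly GRCm38.p6, was used only for names and for which genes are neighbours, and no coordinates are given because no genome build is stated for the table. The probe set with the highest mean over all arrays stood for each of 18193 genes, of which 9010 had more than 1 probe set. Both probe sets that carry the symbol Rybp also carry that of its pseudogene. They were tested as extra entries, 18195 in all, because Rybp is the targeted gene. Probe sets with several symbols or none were tested apart.

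Differences were tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3) by a linear fit to the log2 values of all 16 arrays with the 4 groups and the clone as terms, empirical Bayes moderation and Benjamini-Hochberg adjustment. A gene was taken as higher or lower at an adjusted p under 0.05. The contrasts were KO against control at each day, the difference of these effects between the days, and untreated cells at day 12 against day 4. The difference of the KO effect between clones came from a fit with a mean for each clone and group. Errors given with a log2 fold change are standard errors, and those given with an intensity are SD with n = 4 arrays. The log2 transformation and the extra entries for Rybp followed from what the table holds. The rest of the fit, the comparisons and the gene lists were fixed before the data were examined.

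The 22 gene lists were PRC1 components, PRC2 components, pluripotency, germline and meiosis, 2-cell stage and preimplantation, Hox genes, Polycomb-target transcription factors, primitive endoderm, trophectoderm, mesoderm, ectoderm and neural, primed epiblast, feeder fibroblast markers, imprinted genes, p53 targets and cell cycle inhibitors, DNA methylation and retroviral silencing, interferon response, cholesterol synthesis, glycolysis and hypoxia, FGF-ERK feedback, amino acid stress response, and housekeeping. Each was tested with camera, which asks whether the genes of a list move further than other genes, at a preset correlation between genes of 0.01 and adjusted over the 22 lists. Camera was also run with the correlation estimated from the data, and fry was run beside it. The genes named for KO against control were Rybp, then the 10 largest increases and the 10 largest decreases among genes past the threshold with the same sign in all 4 pairs of a day, then the 3 members of each list with the largest change. For the other comparisons they were the 3 largest changes in each direction. List members named beyond these were chosen after their values were seen.

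Control and KO arrays of a clone, day and replicate number were checked for pairing over 10000 genes with a mean log2 level above 7. The deviations from the fit with the 4 groups and the clone as separate terms correlated at 0.652 to 0.695 within the 4 pairs of day 4 and at 0.149 to 0.393 within those of day 12. Every correlation was above 0.1, so control and KO arrays of a clone, day and number deviated together, and they are called pairs here. Arrays of the other clone with the same number were not compared. A difference between numbers shared by both clones would give such correlations too. So would a difference between clones that varies with the day, since the fit had no such term. Arrays of the same clone and day with the other number were not compared either. The pairing comes from the data, and no label says what a number stands for. In fits of each day with clone and replicate number as terms, the replicate numbers differed in 5658 of these genes at day 4 and in 1452 at day 12. KO and control differed in 641 and 2214 of these genes in the same fits. Results of the fit with the 8 pairs as a block are given where the count of genes moves by more than 1.5 times or the call of a printed fold change differs. Replicates of a clone and group correlated at 0.896 to 0.928 over all probe sets.

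The fits were tested on simulated data with 18193 genes and 50 changed genes per size, 100 for the difference between the days. For KO against control at day 4, 28% of genes changed by 1 on the log2 scale, 60% of those changed by 2 and 92% of those changed by 4 were recovered, with 7 false calls among 104. At day 12 these shares were 24%, 58% and 86%, with 4 false calls among 89. For the difference of the KO effects between days they were 18%, 45% and 82%, for untreated cells over time 38%, 62% and 88%, and for the clone difference 0%, 24% and 52% at day 4. A simulated shift of 0.5 in a list of 20 genes was found by camera, by camera with an estimated correlation and by fry, with 0 of the other lists called. The simulated genes varied independently of each other, so this cannot show false calls that arise from correlated genes. Alternatives covered the probe set of a gene, a filter on dim genes, normalization, the variance model, array weights, the covariates, the arrays and clones used, the thresholds, the set test, and leaving out each array in turn. The offset, the floor, the cyclic loess, the centring on housekeeping genes, the fits of either replicate number alone and the primitive endoderm term were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.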

Results

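The study asked which genes change when ES cells lose Rybp, a subunit of variant forms of PRC1 that binds Ring1 proteins and the transcription factor Yy1. Polycomb complexes keep developmental genes silent in ES cells. Transcripts of 18193 genes were measured on 16 arrays. Control and KO cells of clones 10 and 15 were sampled at day 4 and at day 12, with 4 arrays per group. Intensities are the deposited linear values, and fold changes come from the fit to their log2 values.

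The targeted transcript fell sharply in both clones at both days. Probe set 1421111_at, annotated to both Rybp and its pseudogene, had an intensity of 2753 ± 609 (SD, n = 4) in control and 97.4 ± 18.5 in KO cells at day 4, a log2 fold change of -4.81 ± 0.24 (limma adjusted p = 1.3e-06). At day 12 it read 3029 ± 334 in control and 189 ± 74.6 in KO cells, a log2 fold change of -4.09 ± 0.24 (limma adjusted p = 2.6e-06). The lowest control array read 2047 and the highest KO array 255.7, so the arrays of the 2 conditions did not overlap. The other probe set, 1428219_at, did not fall. It read 1363 ± 1282 in control and 6002 ± 1840.3 in KO cells at day 4 (log2 fold change 2.82 ± 0.74, limma adjusted p = 0.154), and 959.9 ± 963 against 4199 ± 997 at day 12 (2.95 ± 0.74, limma adjusted p = 0.0518). Its control level depended on the clone, with a mean of 2449 in clone 10 and 276 in clone 15 at day 4, and of 1756 and 164 at day 12. Probe sequences and the deleted exons are not given, so a probe set outside the deleted part would check nothing. Within clone 15 alone the fall of 1421111_at was -4.76 at day 4, with a limma adjusted p of 0.0780, and within clone 10 alone it was -4.86 (limma adjusted p = 0.0341).

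**Figure D1:**
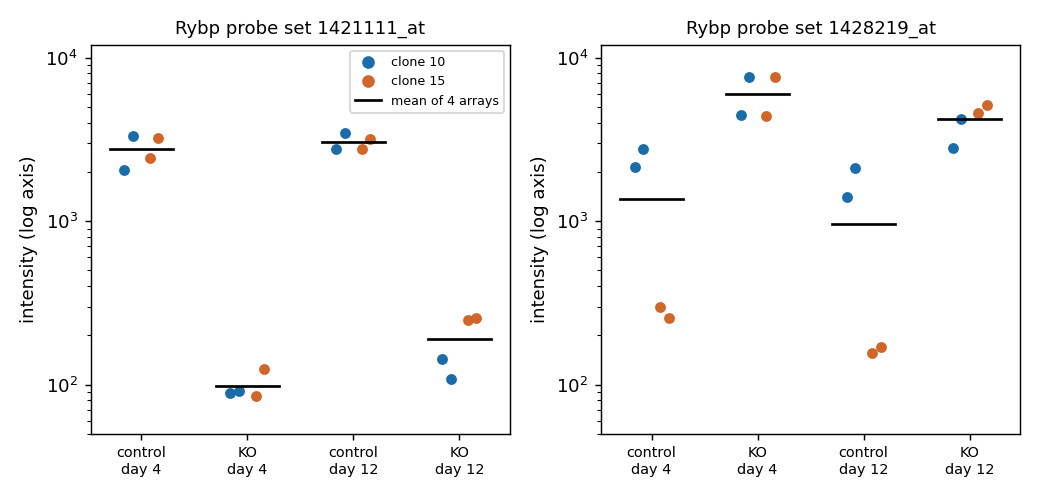
Deposited intensity (log axis) of both probe sets annotated to Rybp, 1 dot per array coloured by clone, with a bar at the mean of 4 arrays per group. On 1421111_at every KO array lies below 255.7 or at it and every control array at 2047 or above, while on 1428219_at the KO arrays lie above the controls of both clones and the clone 15 controls lie lowest.

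At day 4 the loss of Rybp was accompanied mainly by increases, the largest in genes that were near background in control cells. Gm20767 read 2.99 ± 1.62 in control and 1200.3 ± 633 in KO cells, a log2 fold change of 8.73 ± 0.67. BC080696 read 5.07 ± 3.02 against 1576 ± 788 (8.32 ± 0.60) and AF067061 29.3 ± 36.3 against 4151 ± 2695 (7.59 ± 0.66). Ubtfl1, an HMG-box gene of the preimplantation embryo, reached 493 ± 229 (6.32 ± 0.78) and Usp17la, a deubiquitinating enzyme, 3165 ± 2392 (5.76 ± 0.50). With every value under 28.3 raised to it, the folds of these 5 genes were 38.8, 50.9, 94.7, 16.3 and 48.4. The other named increases were Gm11544 (6.14), Gm4850 (5.38), Pramel18 of the Prame-like family (4.87), Ccser1 (4.52) and 3110040M04Rik (3.85) on the log2 scale, with floored folds of 31.6, 14.3, 12.05, 6.58 and 12.4. All 10 were higher in KO in 4 of 4 pairs, which the choice of named genes required, with limma adjusted p from 2.6e-05 to 0.00716. A second, dimmer probe set of Ccser1 read a log2 fold change of 0.33 (limma adjusted p = 0.999). The probe set of AF067061, 1425220_x_at, carries the suffix of sets whose probes match further transcripts. The 3' over 5' signal of the transferrin receptor control, a sign of RNA integrity, was also higher in KO in 4 of 4 pairs of day 4 (by 0.20 ± 0.14, SD) and in 1 of 4 pairs of day 12 (-0.02 ± 0.10). At day 4 the shifts of the other controls were 0.03 ± 0.03 for actin, 0.01 ± 0.05 for Gapdh and -0.03 ± 0.45 for pyruvate carboxylase.

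Fewer genes fell at day 4, and by less. Slc46a3, a lysosomal transporter, went from 207 ± 32.8 to 96.8 ± 8.55 (log2 fold change -1.08 ± 0.19), Cnpy1, a regulator of FGF signalling, from 1235 ± 201 to 671 ± 116 (-0.88 ± 0.17), and Slc6a15, a neutral amino acid transporter, from 518 ± 31.1 to 301 ± 13.5 (-0.78 ± 0.14). The imprinted gene Nnat (-0.76), the endoplasmic reticulum protein gene Ccpg1 (-0.55), Anp32a (-0.52) and the MAP kinase pathway kinase gene Braf (-0.48) fell too. Other probe sets read -0.74 and -0.79 for Cnpy1, -0.14 for Ccpg1, -0.56 and -0.39 for Anp32a and from -0.55 to -0.11 for Braf, and for the last 3 genes no probe set passed limma over every probe set. The decreases in Gm11559 (-3.13), the magnesium transporter gene Slc41a2 (-2.80) and the testis-specific linker histone gene H1f6 (-2.62) started from control means of 19.2, 38.6 and 51.5. With the floor at 28.3 they shrank to 1.06-fold, 1.33-fold and 1.75-fold. All 10 were lower in 4 of 4 pairs, which their choice required, at limma adjusted p from 0.00771 to 0.0490. Only H1f6 stayed under 0.05 in every fit without 1 of the 16 arrays. The call of Braf was lost in 14 of these 16 fits, at limma adjusted p up to 0.112. Gm11559 (limma adjusted p = 0.0508), Slc46a3 (0.0698) and Ccpg1 (0.0939) did not pass with the 8 pairs as a block. Tested over every probe set, Gm11559 (limma adjusted p = 0.0550), Slc41a2 (0.0591), Slc6a15 (0.0574) and Nnat (0.0628) also missed the threshold.

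In all, limma found 103 genes higher and 10 lower in KO cells at day 4, of which 78 and 4 changed at least 2-fold, and 1552 genes had an unadjusted p under 0.05. With the 8 pairs as a block, 134 genes were higher and 43 lower, and 80 of the 113 genes were found by both fits. Parting the day 4 arrays by replicate number instead gave 4150 genes. Without KO day 4 array clone 10 replicate 1, clone 15 replicate 1 or clone 15 replicate 2, 64, 62 and 65 genes were higher. The count of genes lower was 2 and 3 without control day 4 clone 10 replicate 1 and clone 15 replicate 1, and 4, 3, 1 and 4 without KO day 4 clone 10 replicate 1, clone 15 replicate 1, clone 10 replicate 2 and clone 15 replicate 2. It was 4, 5 and 4 without KO day 12 clone 10 replicate 1, clone 15 replicate 1 and clone 10 replicate 2, and 5 without control day 12 clone 15 replicate 2.

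Of the 22 lists, germline and meiosis had the most members past the threshold at day 4, and it is among the longer lists. Of 54 measured members of the germline and meiosis list, 13 rose and 0 fell (23 rose and 1 fell adjusted over the list alone), and the median log2 fold change was 0.83 (camera adjusted p = 4.6e-21, and 0.00153 with an estimated correlation). Sycp1, a synaptonemal complex protein, rose from 74.3 ± 26.8 to 386 ± 109.7 (log2 fold change 2.41 ± 0.25), the homeobox gene Rhox13 from 164 ± 27.7 to 858 ± 188 (2.37 ± 0.26), and Tex101, a sperm surface protein, from 12.9 ± 4.21 to 102 ± 57.7 (2.75 ± 0.45, and 3.08-fold with the floor at 28.3). The germ cell RNA-binding gene Dazl (1.83 ± 0.19), the germ cell helicase gene Ddx4 (1.74 ± 0.19), and the piRNA pathway genes Mael (2.09 ± 0.14) and Piwil2 (1.15 ± 0.17) also rose. In the 2-cell stage and preimplantation list, 5 of 32 measured members rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 2.2e-12, 0.0015 with an estimated correlation). These 5 were Ubtfl1, Usp17la, Zfp352 (2.62 ± 0.21), Spz1 (2.23 ± 0.42) and Sp110 (1.70 ± 0.22), while Tcstv1 read 3.85 ± 0.85 without passing (limma adjusted p = 0.0756). The list names 55 genes, and its counts use only probe sets with a single symbol. Probe sets with several symbols, which include Zscan4 genes of this list, were tested apart. Tex101 (limma adjusted p = 0.0780) and Spz1 (0.0801) did not pass with the 8 pairs as a block. Of 28 trophectoderm genes, markers of the embryo's outer layer, the homeobox gene Rhox6 rose from 440.0 ± 63.4 to 1207 ± 83.7 (1.46 ± 0.14). In that list 3 rose adjusted over the list alone and the median was 0.33 (camera adjusted p = 3.2e-04, 0.00919 with an estimated correlation). These 3 list shifts of day 4 stand beside the higher 3' over 5' signal of the transferrin receptor control in KO arrays, which Gapdh and pyruvate carboxylase did not share (higher in 2 of 4 pairs each).

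A pair of smaller list shifts at day 4 did not hold with an estimated correlation. The feeder fibroblast markers, which would rise with more feeder cells in a sample, had a median of 0.16 over 40 members (camera adjusted p = 0.0128, and adjusted p = 0.224 with an estimated correlation). Of these Igfbp3, a growth factor binding protein, rose from 283 ± 49.98 to 1109 ± 483 (log2 fold change 1.88 ± 0.27), 1 rose adjusted over the list alone, and the fibroblast collagens Col1a1, Col1a2 and Col3a1 read 0.38, -0.14 and 0.07. The 16 primed epiblast genes, which mark the later pluripotent state, had a median of -0.30 with 0 past the threshold by limma over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0361, and adjusted p = 0.224 with an estimated correlation). Zic2 (-1.35), Dkk1 (-1.02) and Otx2 (-0.85) had the largest values. The feeder shift missed 0.05 without KO day 4 clone 10 replicate 1 (0.0540), KO clone 15 replicate 1 (0.0629) or control clone 15 replicate 2 (0.0550). The primed epiblast shift missed it without KO clone 10 replicate 1 (0.172), KO clone 15 replicate 1 (0.0739), control clone 10 replicate 2 (0.186) or control clone 15 replicate 2 (0.145). The 3' over 5' signal of the transferrin receptor control was 1.06 ± 0.09 on the log2 scale in control and 1.26 ± 0.19 in KO arrays of that day, higher in KO in 4 of 4 pairs (by 0.08 to 0.34), against 0.48 ± 0.08 and 0.50 ± 0.05 for actin.

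The other 17 lists did not pass the camera threshold at day 4, which does not show that they were unchanged. Among imprinted genes, Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases, rose from 348 ± 35.9 to 812 ± 57.3 (log2 fold change 1.23 ± 0.25), Ndn rose by 0.81 and Nnat fell. That list had 29 members, 3 higher and 1 lower adjusted over the list alone, and a camera adjusted p of 0.0594, which was 0.04998 without KO day 12 clone 10 replicate 1 and 0.0485 without KO day 12 clone 10 replicate 2. Cdkn1c was also the only riser among 28 p53 targets and cell cycle inhibitors (camera adjusted p = 0.775, 2 higher adjusted over the list alone). Of 35 primitive endoderm genes 2 rose, Serpinh1 (0.87 ± 0.15) and P4ha2 (1.10 ± 0.15), both collagen-modifying proteins, with 3 adjusted over the list alone and a camera adjusted p of 0.397. P4ha2 was the 1 riser of 29 glycolysis and hypoxia genes in both counts (camera adjusted p = 0.544), and that list passed as lower without KO day 4 clone 10 replicate 2 (camera adjusted p = 0.0341). The PRC1 subunit gene Phc2 rose from 335 ± 77.3 to 643 ± 73.3 (0.97 ± 0.19), the 1 of 25 PRC1 components in both counts (camera adjusted p = 0.923). Fbxo15 rose by 0.58 among 34 pluripotency genes, with 2 higher adjusted over the list alone (camera adjusted p = 0.397).

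No member passed over all genes by limma in 11 of these 17 lists at day 4. They were PRC2 components (11 members, camera adjusted p = 0.775), Hox genes (33 members, 0.923), Polycomb-target transcription factors (68 members, 0.923), mesoderm (25 members, 0.923), ectoderm and neural (27 members, 0.546), DNA methylation and retroviral silencing (27 members, 0.696), interferon response (31 members, 0.541), cholesterol synthesis (20 members, 0.434), FGF-ERK feedback (21 members, 0.369), amino acid stress response (27 members, 0.874) and housekeeping (26 members, 0.862). Adjusted over the list alone, 2 interferon response genes were higher, 1 mesoderm and 1 FGF-ERK feedback gene were lower and the other 8 lists had 0. The interferon genes nearest the threshold were Xaf1 (0.77, limma adjusted p = 0.0622) and Psmb9 (0.69, 0.0556), and the FGF feedback gene nearest it was Il17rd (-0.45, 0.0663). These 3 passed with the 8 pairs as a block, at limma adjusted p = 0.0383, 0.0486 and 0.0463. Members that did not pass, each among the 3 largest values of its own list, were Hoxa2 (-2.10), Irx5 (2.17), Evx1 (-1.76), Gfap (-1.99), Ezh1 (-0.42), Dnmt3a (-0.35), Hmgcs1 (-0.27), Cebpb (0.53) and Gusb (0.54). The median, the mean and the camera test differed in sign for the PRC1 (median -0.04, mean 0.02), PRC2, Hox (0.19, 0.05, camera down), Polycomb-target (-0.02, 0.09, camera down), mesoderm (0.15, 0.04, camera down), ectoderm (0.06, -0.06), p53 (-0.07, 0.02) and housekeeping lists.

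**Figure D2:**
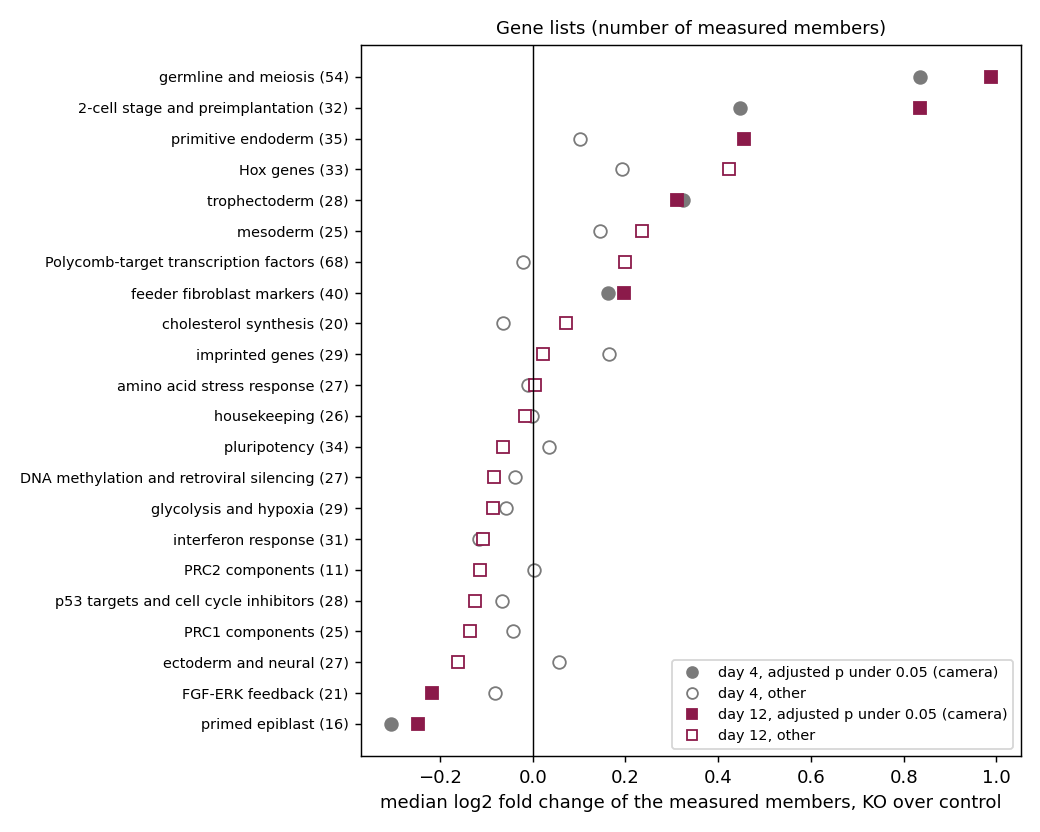
Median log2 fold change of KO over control for each gene list (number of measured members in parentheses), circles for day 4 and squares for day 12, filled where the camera adjusted p was under 0.05. The germline and meiosis list has the highest median at both days (0.83 and 0.99), followed by the 2-cell stage and preimplantation list (0.45 and 0.83).

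By day 12 the increases seen at day 4 were still present and many more genes differed. AF067061 read 17.8 ± 10.97 in control and 7592 ± 1191 in KO cells (log2 fold change 8.90 ± 0.66), Gm20767 11.2 ± 13.6 against 2096 ± 137 (8.23 ± 0.67), Gm11544 19.03 ± 21.6 against 1621 ± 355 (7.26 ± 0.72) and BC080696 17.8 ± 13.9 against 1930.1 ± 287 (7.19 ± 0.60). With the floor at 28.3 their folds were 254, 72.01, 48.99 and 65.9. Pramel18 (6.31), Usp17la (6.06), Ubtfl1 (5.65), Gm4850 (5.36), 0610040J01Rik (4.84) and the X-linked, testis-expressed gene Tex13b (4.49) completed the 10 largest, with floored folds of 21.8, 66.7, 23.3, 17.3, 10.04 and 12.1. All 10 were higher in 4 of 4 pairs, which their choice required, with limma adjusted p from 1.7e-05 to 0.0385. The exception to their stability was 0610040J01Rik, which lost its call in 11 of the 16 fits without an array, at limma adjusted p up to 0.109, and with the 8 pairs as a block (limma adjusted p = 0.0616). Tested over every probe set, this gene missed the threshold too (limma adjusted p = 0.0580).

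**Figure D3:**
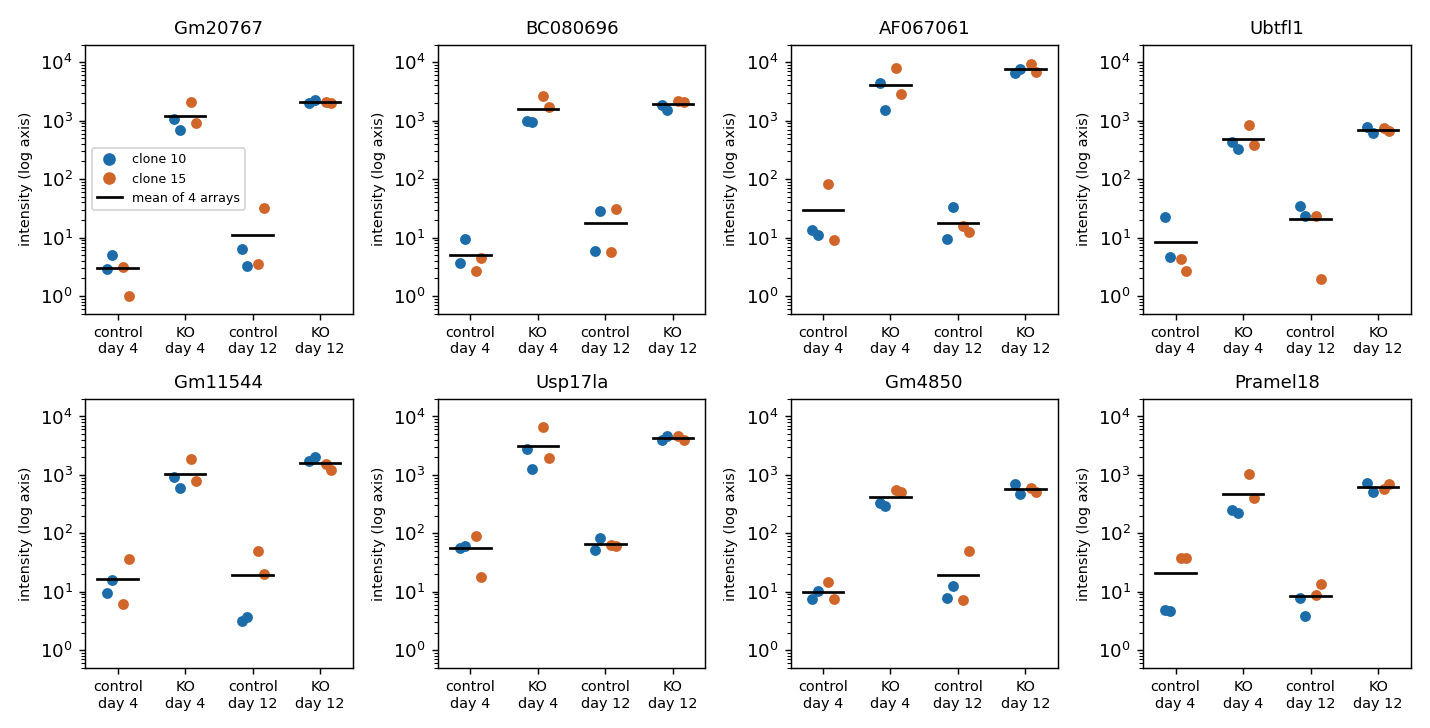
Deposited intensity (log axis) of 8 genes that were among the 10 largest increases at both days, 1 dot per array coloured by clone, with a bar at the mean of 4 arrays. In each panel every KO array lies above every control array, as for Usp17la with means of 55.7 and 3165 at day 4 and 64.7 and 4267 at day 12.

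Among the decreases at day 12, a pair of transcription factor genes stood out by their level. Myb, best known from blood progenitors, went from 1565 ± 248 to 461 ± 67.6 (log2 fold change -1.76 ± 0.26, limma adjusted p = 0.00298), and its other probe sets read -1.85 and -1.87. Otx2, a homeobox gene of the primed epiblast and the anterior brain, went from 1914 ± 281 to 585 ± 35.5 (-1.70 ± 0.25, limma adjusted p = 0.00267). The other 8 named decreases had control means of 116 or less. They were the ion exchanger gene Slc24a4 (-2.90), the epidermal transcription factor gene Zfp750 (-2.88), B3gnt9 (-2.66), Asb11 (-2.51), Lgi4 (-2.29), Tmem262 (-2.27), Igkv1-135 (-2.23) and Ppm1e (-1.999). With the floor these decreases shrank to 2.13-fold, 3.52-fold, 1.18-fold, 2.54-fold, 1.05-fold and 1.43-fold, Igkv1-135 was at the floor in both groups, and Ppm1e fell 1.13-fold. All 10 were lower in 4 of 4 pairs, which their choice required. Myb, Otx2 and Asb11 stayed past the threshold in every fit without 1 array. Tested over every probe set, Lgi4 (limma adjusted p = 0.0631), Tmem262 (0.0613) and Igkv1-135 (0.0736) missed it.

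In total limma found 399 genes higher and 163 lower at day 12, of which 232 and 35 changed at least 2-fold, with 2697 genes at an unadjusted p under 0.05. With the 8 pairs as a block these counts were 852 and 626, and 532 of the 562 genes were found by both fits. Without KO day 12 clone 10 replicate 1, KO clone 15 replicate 1, control clone 15 replicate 2 or KO clone 15 replicate 2, 202, 232, 263 and 263 genes were higher. Leaving out any of the 8 arrays of the day gave between 83 and 103 genes lower.

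More germline and preimplantation genes passed at day 12, which by itself does not show a stronger response there. Of the 54 germline and meiosis genes 23 rose and 1 fell (29 and 3 adjusted over the list alone), with a median log2 fold change of 0.99 (camera adjusted p = 9.2e-17, 0.00396 with an estimated correlation). Tex101 rose from 11.6 ± 3.47 to 138 ± 21.6 (3.60 ± 0.45, 4.83-fold with the floor at 28.3), Rhox13 from 130.2 ± 41.6 to 1146 ± 256 (3.17 ± 0.26) and the testis ADP/ATP carrier gene Slc25a31 from 61.01 ± 21.03 to 512 ± 85.6 (3.12 ± 0.31). Dazl (2.91 ± 0.19) and Stra8, a gene needed to enter meiosis (2.72 ± 0.22), rose as well, whereas Prdm1, needed to specify primordial germ cells, fell (-0.83 ± 0.15). In the 2-cell stage and preimplantation list 14 of 32 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 1.7e-12, 0.00143 with an estimated correlation). Beside Usp17la and Ubtfl1 these included the arginase gene Arg2 (25.1 ± 17.01 to 431 ± 63.5, 4.46 ± 0.94), Spz1 (4.23 ± 0.42), Tcstv1 (4.00 ± 0.85) and Zfp352 (3.19 ± 0.21). With the floor the folds of Arg2, Spz1 and Tcstv1 were 13.3, 4.14 and 4.89.

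Some genes of the extraembryonic lineages were higher too. Of 28 trophectoderm genes 6 rose and 0 fell in both counts, over all genes and adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.00278, 0.0274 with an estimated correlation). Rhox6 went from 651 ± 90.8 to 2253 ± 290.2 (log2 fold change 1.79 ± 0.14) and the transcription factor gene Gata3 from 8.54 ± 3.28 to 47.5 ± 18.4 (2.47 ± 0.42). Cdx2, a regulator of trophectoderm identity, read 7.34 ± 4.57 in control and 46.7 ± 32.3 in KO cells (2.55 ± 0.46), but its control level at day 4 had been 42.5 ± 5.79 and its KO level 30.5 ± 8.35. With the floor at 28.3 Gata3 rose 1.59-fold and Cdx2 1.62-fold. Plac1 (1.64 ± 0.35), Igf2 (1.21 ± 0.21) and Rhox9 (1.06 ± 0.24) were the remaining risers. Of 35 primitive endoderm genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 2.0e-05, but adjusted p = 0.241 with an estimated correlation). The list mean was higher in KO in 3 of 4 pairs, from -0.07 to 0.88. The risers were P4ha2 (1.17 ± 0.15), the endocytic receptor genes Lrp2 (1.14 ± 0.23) and Amn (1.08 ± 0.20), the lineage transcription factor gene Gata6 (0.98 ± 0.24) and Serpinh1 (0.72 ± 0.15). Pdgfra (1.56) and Cubn (1.34) did not pass. Gata6 did not pass with the 8 pairs as a block (limma adjusted p = 0.0526) and Pdgfra did (0.0453).

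Beside these groups, 3 lists shifted by small amounts, none with an estimated correlation. The primed epiblast list had a median of -0.25 over 16 genes with Otx2 the 1 gene that fell (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0321, adjusted p = 0.241 with an estimated correlation). In the FGF-ERK feedback list the median was -0.22 over 21 genes and Il17rd, an inhibitor of FGF receptor signalling, fell by 0.71 ± 0.10, the 1 gene in both counts, also adjusted over the list alone (camera adjusted p = 0.0154, adjusted p = 0.241 with an estimated correlation). The feeder fibroblast markers had a median of 0.20 over 40 genes (camera adjusted p = 0.0284, adjusted p = 0.241 with an estimated correlation). Igfbp3 rose from 348 ± 34.7 to 1119 ± 217 (1.67 ± 0.27), with 2 genes higher adjusted over the list alone, while Col1a1, Col1a2 and Col3a1 read 0.21, -0.10 and 0.12. The primed epiblast shift missed 0.05 without control day 12 clone 10 replicate 1 (0.0679), control clone 10 replicate 2 (0.103), KO clone 10 replicate 2 (0.0846) or control clone 15 replicate 2 (0.0816). The feeder shift missed it without control clone 10 replicate 1 (0.110), KO clone 10 replicate 2 (0.0846) or KO clone 15 replicate 2 (0.126).

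The other 15 lists did not pass the camera threshold at day 12, which does not show that they were unchanged, and single members passed limma. Among 68 Polycomb-target transcription factors 4 rose (Foxa1 3.14 ± 0.72, 2.19-fold with the floor, Cdx2, Gata3 and Gata6) and 2 fell (Otx2 and Olig1, -0.76 ± 0.15), 6 and 3 adjusted over the list alone (camera adjusted p = 0.514). Of 29 imprinted genes Cdkn1c (1.53 ± 0.25), the growth factor gene Igf2 (1.21), Ndn (0.97) and Phlda2 (0.76) rose and Nnat fell (-0.92 ± 0.14), with the same counts of 4 and 1 adjusted over the list alone (camera adjusted p = 0.477). Of 34 pluripotency genes Tbx3 (1.22 ± 0.23), Fbxo15 (1.04 ± 0.11), Dppa2 (0.90 ± 0.15) and Tcl1 (0.56) rose and Utf1 fell (-0.82), 7 and 3 adjusted over the list alone (camera adjusted p = 0.922). In the Polycomb complexes themselves, Phc2 (0.91 ± 0.19) and E2f6, a transcription factor of a variant PRC1 (0.69 ± 0.17), rose among 25 PRC1 components, with 2 adjusted over the list alone (camera adjusted p = 0.598). Ezh1, a catalytic subunit gene of PRC2, fell by 0.64 ± 0.14 among 11 PRC2 components, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.160).

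In the remaining lists at day 12 few genes passed. Of 31 interferon response genes Xaf1 (1.37 ± 0.16) and the immunoproteasome gene Psmb9 (0.74) rose and Ddx58, a sensor of viral RNA, fell (-0.53), 5 and 3 adjusted over the list alone (camera adjusted p = 0.922). Of 27 amino acid stress response genes the cationic amino acid transporter gene Slc7a3 fell by 0.67 ± 0.13, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.359). Zfp809, needed to silence retroviruses, rose by 0.75 ± 0.13 as the 1 gene of 27 in the DNA methylation and retroviral silencing list in both counts (camera adjusted p = 0.299). Wnt5a fell by 0.86 among 25 mesoderm genes, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.658), and Otx2 was the 1 that fell among 27 ectoderm and neural genes, with 2 lower adjusted over the list alone (0.160, and 0.0454 without control day 12 clone 15 replicate 1). P4ha2 among 29 glycolysis and hypoxia genes (camera adjusted p = 0.299, 1 higher and 1 lower adjusted over the list alone), Cdkn1c among 28 p53 targets and cell cycle inhibitors (0.299, 1 higher) and Alas1, the first enzyme of haem synthesis, among 26 housekeeping genes (0.922, 1 higher) were the single risers. Hox genes (median 0.42 over 33 genes, camera adjusted p = 0.3005) and cholesterol synthesis (0.07 over 20 genes, 0.401) had 0 genes past the threshold by limma over all genes, and 0 and 1 adjusted over the list alone. Hoxb13 (1.86), Hoxc9 (1.30), Mvk (0.48), Lmo2 (2.48), Zic1 (2.30), Ifit3 (-1.92), Bbc3 (-0.90), Pdk1 (-0.55) and Mtf2 (0.46) did not pass, each among the 3 largest values of its own list. Mvk (limma adjusted p = 0.0429), Ifit3 (0.0195), Bbc3 (0.00221) and Pdk1 (0.00751) did with the 8 pairs as a block. Median, mean and camera differed in sign for the pluripotency (-0.07, 0.04), interferon response (-0.11, 0.03, camera down), amino acid stress response (0.00, -0.08) and housekeeping (-0.02, 0.02) lists.

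The genes that changed at day 4 had largely changed the same way at day 12. Of the 103 genes higher at day 4, 87 were higher at day 12 as well, among them the 8 genes that led both days, against 2.26 expected for independent lists of these sizes (one-sided Fisher's exact test, p = 3.9e-131). Of the 10 lower at day 4, 6 were lower at day 12, against 0.0896 expected (one-sided Fisher's exact test, p = 9.6e-11). Both tests treat genes as independent, so their p-values do not measure the spread between arrays. Both days also share 1 estimate of the spread of each gene, which can by itself bring shared calls. No gene changed in opposite directions by limma, and all 103 and all 10 kept the sign of their fold change at day 12. The 312 genes that passed as higher at day 12 but not at day 4 were positive at day 4 in 293 cases, and the 399 genes higher at day 12 had a median log2 fold change of 0.61 at day 4 and 1.14 at day 12. These 399 were chosen for passing at day 12, which can by itself raise their median there above that of day 4. With the 8 pairs as a block 151 genes, in place of 93, changed the same way at both days. Without KO day 4 clone 10 replicate 1, clone 15 replicate 1 or clone 15 replicate 2, it was 61, 57 and 60.

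A direct test of the difference between the days found 0 genes by limma, with 832 at an unadjusted p under 0.05. So the larger number of genes at day 12 does not show that any single gene responded more strongly there. With the 8 pairs as a block 1 gene passed, Tmlhe, an enzyme of carnitine synthesis (day 12 minus day 4, 2.37 ± 0.17, limma adjusted p = 0.0341), which was named after its value was seen. Over the genes higher at day 4 the median change from day 4 to day 12 was 0.13. Fold changes at both days correlated at r = 0.306 across genes, which are not independent replicates.

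No gene was found to respond differently in clones 10 and 15. The KO effect differed between clones for 0 genes by limma at day 4 (569 at an unadjusted p under 0.05) and for 0 at day 12 (525). In simulated data the day 4 test recovered 24% of genes that differed by 2 on the log2 scale, so a difference of that size would mostly be missed. The Rybp probe set 1428219_at had the larger clone difference of the pair, 3.13 ± 0.51 higher in clone 15 at day 4 and 3.89 ± 0.51 at day 12, without passing (limma adjusted p = 0.343 and 0.241). Across genes the fold changes of clone 10 and clone 15 correlated at r = 0.163 at day 4 and 0.255 at day 12, and at 0.381 and 0.526 when dim genes were left out.

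Untreated cells also changed between day 4 and day 12 of culture. Tfec, a transcription factor of the MiT family, rose from 4.598 ± 0.916 to 97.3 ± 8.67 (log2 fold change 4.42 ± 0.58, limma adjusted p = 0.00329), Nostrin, a regulator of nitric oxide synthase trafficking, from 11.3 ± 3.85 to 161 ± 41.5 (3.87 ± 0.41, limma adjusted p = 6.7e-04), and the cytokine gene Tslp from 5.64 ± 2.82 to 68.6 ± 22.8 (3.77 ± 0.65, limma adjusted p = 0.0156). Cdx2 fell from 42.5 ± 5.79 to 7.34 ± 4.57 (-2.76 ± 0.46, limma adjusted p = 0.0142), B230303A05Rik from 27.9 ± 9.13 to 5.42 ± 2.73 (-2.45 ± 0.45, limma adjusted p = 0.0225) and Lcn12 from 21.9 ± 4.95 to 4.88 ± 2.48 (-2.30 ± 0.49, limma adjusted p = 0.0495). With the floor of 28.3 Tfec rose 3.43-fold, Nostrin 5.57-fold and Tslp 2.33-fold, Cdx2 fell 1.49-fold and B230303A05Rik 1.12-fold, and Lcn12 lay under it in both groups. In total 119 genes were higher and 62 lower at day 12. With replicate number as a term, since pairs do not span the days, 487 genes passed in place of 181. Fewer genes passed without control day 4 clone 10 replicate 1 (115), clone 10 replicate 2 (98) or clone 15 replicate 2 (100), or without control day 12 clone 10 replicate 1 (94), clone 10 replicate 2 (95) or clone 15 replicate 2 (103). The day 12 controls stand in both this comparison and KO against control at day 12, so chance values of those arrays enter both with opposite sign.

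**Figure D4:**
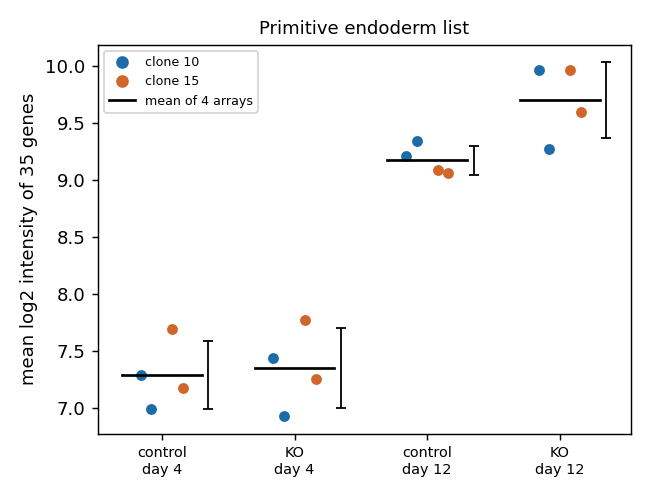
Mean log2 intensity of the 35 primitive endoderm genes on each array, coloured by clone, with a bar at the mean of 4 arrays per group and an error bar of 1 SD. All 8 arrays of day 12 lie above all 8 arrays of day 4.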

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

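The comparisons of the 2-cell and germline genes with a noise floor, with primitive endoderm genes and with OHT-treated controls, those of the second Rybp probe set, and the regrouping of both days that keeps the pairs, were chosen only after these results were seen; the other regroupings of the arrays were planned.

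Genes of the 2-cell stage and the germline were higher in KO cells at both days. Signal near the noise floor was tested by raising every value under 28.3 to it. The mean change of all 86 members of the lists, 0.97 at day 4 and 1.25 at day 12 on the log2 scale, was then 0.80 ± 0.09 and 1.06 ± 0.13 (SD of 4 pairs), so noise does not bring most of it. A larger share of primitive endoderm-like cells would raise that lineage too, and its list mean moved by 0.06 ± 0.09 (SD of 4 pairs) at day 4. The germline list mean exceeded the primitive endoderm list mean by 0.78 ± 0.05 on the log2 scale (SD of 4 pairs) at day 4. Genes near background can move further on this scale than genes already expressed, so the size of this excess decides nothing. At day 12 the excess was 0.57 ± 0.55, which alone decides nothing. Over time in untreated cells, however, the primitive endoderm mean rose by 1.89 ± 0.39, further than by 0.53 ± 0.42 in KO at day 12. All 86 members, higher in KO at day 12 by 1.25 ± 0.17, read -0.05 ± 0.15 over that time. This argues against such a share as the source of the mean rise of the 86 members. The 37 members higher in KO at day 12, by 2.61 ± 0.26, read -0.23 ± 0.18 over that time. They were chosen with the day 12 controls that also enter the change over time, which can lower that value. RNA integrity was not tested as a source and stays open. Its transferrin receptor control was higher in KO arrays in 4 of 4 pairs of day 4 (0.20 ± 0.14), where actin moved by 0.03 ± 0.03, Gapdh by 0.01 ± 0.05 and pyruvate carboxylase by -0.03 ± 0.45. At day 12, with the lists as high or higher, the transferrin receptor moved by -0.02 ± 0.10. Effects of OHT or of the recombinase itself stay open, since 0 control arrays were given OHT. A response to the loss of Rybp is a candidate explanation that these tests leave in place, as a hypothesis found and tested on the same arrays.

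The second Rybp probe set, 1428219_at, was higher in KO cells and low in the controls of clone 15. Wrong labels would mix control and KO arrays on the first probe set as well, where the lowest control array read 8.01 times the highest KO array. Noise of a dim probe set does not reach the gap of 3.27 on the log2 scale between the clones among controls, against an SD of 0.37 between arrays of a clone and group. Signal from outside the deleted part or from the pseudogene could explain the rise, and it stays open because the annotation of the probe set holds 2 genes and no probe sequence was analysed here. No biological explanation was tested for this probe set.

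Whether other groupings of the arrays give as much was counted by refitting. For KO against control at day 4, 2 of the 35 splits gave at least the real 113 genes, so chance is not excluded by this count. The other was the split by replicate number, with 4150 genes, which points to a structure of the arrays that the numbers follow, and the highest of the rest was 3. Among the 8 splits that part all 4 pairs, 1 gave as many (real 113, highest other 1), and 8 splits are too few for a share under 0.05. With the 8 pairs as a block 177 genes passed. Of the gene lists at day 4, 5 passed in the real split and up to 7 in another, with 4 of 35 splits at 5 or more, so chance is not excluded for the number of lists.

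At day 12, 1 of 35 splits gave the real 562 genes and the highest other gave 1. Chance is thus excluded as the source of that count only among splits that ignore the pairing and take the arrays as exchangeable. The 8 splits that part all pairs, of which 1 gave as many (highest other 1), are too few for a share under 0.05. For gene lists at day 12, 3 of 35 splits gave the real 7 or more, with up to 9, so chance is not excluded there. For the untreated cells over time 1 of 35 splits gave the real 181 genes and the highest other gave 5. These splits also take the arrays as exchangeable, so chance is excluded only among these regroupings. For genes changed the same way at both days, 1 of 100 drawn pairs of splits gave the real 93 and the highest other gave 0. With the pairs of each day parted throughout, 1 of 64 pairs of splits gave the 93 shared genes and the highest other gave 1. Shared genes cannot outnumber the genes called at either day. Other splits gave at most 3 genes at day 4, apart from the split by replicate number, and at most 1 at day 12. Almost no other pair of splits could thus share many genes, so these counts do not test whether the days agree. For the difference between the days all 100 drawn pairs of splits gave the real 0 or more, with up to 963. More than 5 genes came from 2 of these, 1 of which parted the day 4 arrays by replicate number.

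Single arrays lay far from the other 3 of their group in 15 of 192 groups examined, where 9.6 would be expected by chance. On Rybp probe set 1421111_at, KO day 4 clone 15 replicate 2 read 124.9 against 84.9 to 91.0 in the other 3. Among the largest increases, AF067061 read 83.7 in control day 4 clone 15 replicate 1, Ubtfl1 22.1 in control day 4 clone 10 replicate 1, Gm20767 31.5 and Gm4850 49.7 in control day 12 clone 15 replicate 2, and 0610040J01Rik 49.7 in control day 12 clone 10 replicate 1, each above the other 3 arrays. Among the largest decreases, Zfp750 read 47.2 in KO day 12 clone 15 replicate 2, Asb11 24.4 in KO day 12 clone 10 replicate 1 and Otx2 2333 in control day 12 clone 10 replicate 2, each above the other 3. Below the other 3 were Braf with 939.98 in KO day 4 clone 10 replicate 1 and Igkv1-135 with 9.06 in control day 12 clone 10 replicate 2.

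Among list means on the log2 scale, the 2-cell stage and preimplantation list was high in KO day 12 clone 15 replicate 1 (8.61, others 8.36 to 8.39) and the Polycomb-target list in KO day 4 clone 15 replicate 1 (5.69, others 5.58 to 5.596). The interferon response list was low in control day 12 clone 15 replicate 2 (7.86, others 7.99 to 8.01). The 3' over 5' signal of pyruvate carboxylase was high in control day 12 clone 10 replicate 2 (0.88, others 0.50 to 0.54).

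The KO effect differed between the days for 3 lists by camera, all higher at day 12. The median differences were 0.20 for germline and meiosis (adjusted p = 0.0352), 0.19 for 2-cell stage and preimplantation (0.0425) and 0.21 for primitive endoderm (0.00536). With an estimated correlation none passed (adjusted p = 0.592, 0.444 and 0.592).

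Probe sets that name no single gene changed too. Of 932 probe sets with several gene symbols limma found 13 higher and 1 lower at day 4, and 27 higher and 2 lower at day 12, with 1421111_at among those lower. Probe set 1443961_at, annotated to Gm4340 among others, rose from 135.2 to 15123 at day 4 (log2 fold change 6.83 ± 0.27). Probe set 1457033_at, annotated to Zscan4a, Zscan4c, Zscan4d and Zscan4f among others, rose from 93.1 to 7433 (6.37 ± 0.30), and by 6.67 ± 0.30 at day 12. Probe set 1427479_at, annotated to Eif1a among others, rose by 6.60 ± 0.26 at day 4. These symbols belong to the 2-cell stage and preimplantation list, whose counts use only probe sets with a single symbol. Of 9160 probe sets without a symbol 10 were higher and 0 lower at day 4, and 33 were higher and 26 lower at day 12 by limma. At day 4 1422071_at rose by 5.57 ± 0.64 and 1459989_at by 5.14 ± 0.82, from control means of 11.3 and 14.02, which with the floor at 28.3 is 10.02-fold and 8.81-fold. At day 12 1458062_at and 1443328_at, with control means of 28.1 and 32.3, passed as lower, but with the floor the decreases were only 1.12-fold and 1.16-fold.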

How the results depend on the processing

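The offset of 50 before the log2, the floor at 28.3, the cyclic loess, the centring on the housekeeping list and the fits of either replicate number alone were chosen only after the data were seen. Among the named genes and the lists, 85 fold changes were past the threshold, and none reversed direction under any alternative run. The largest increases and decreases among them were chosen for the same sign in all pairs of a day. That choice fixed their sign in fits of either clone alone or either replicate number alone. Their unchanged sign there is no evidence of stability. Of 120 fold changes of genes and lists that were not past the threshold, 37 changed sign under at least 1 alternative. The direction of such values is thus not settled. Repeating the quantile normalization and centring arrays on the median move nothing, since every array holds the same set of values, and they say nothing about stability. For the KO effects the dim-gene filter, the mean of probe sets and the variance model with trend and robust moderation left all 4 counts of genes higher and lower within 1.5 times.

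The fall of Rybp on 1421111_at kept its direction throughout. It missed the limma threshold in clone 15 alone (-4.76 at day 4, -3.55 at day 12), in arrays numbered 1 alone (-4.69, -3.87) and in arrays numbered 2 alone (-4.93, -4.31) at adjusted p from 0.0780 to 0.167. Clone 10 alone, with as many arrays, passed (-4.86, -4.63), with a fall at day 4 close to that of clone 15. These fits do not settle what part the number of arrays plays, and the cause was not tested. Without each array in turn it ranged from -4.92 to -4.65 at day 4 and from -4.22 to -3.89 at day 12, past the threshold each time.

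Counts in the order day 4 higher, day 4 lower, day 12 higher, day 12 lower, both days, and untreated cells over time are 103, 10, 399, 163, 93 and 181. Fits of fewer arrays found fewer genes. The 8 arrays of the day gave 34, 1, 194, 54 and 25 for the first 5. Clone 10 alone gave 4, 0, 34, 2, 4 and 0, clone 15 alone 0 for each, and the arrays numbered 1 alone or 2 alone 0 for each. By construction a stricter threshold gives fewer: an adjusted p under 0.01 gave 51, 1, 162, 43, 49 and 53, and at least 2-fold 4 of the day 4 lower genes, 232, 35 and, over time, 97.

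The replicate block raised counts. Replicate number as a term gave 27 lower at day 4, 298 lower at day 12, 147 at both days and 487 over time. The block of 8 pairs gave 43 lower at day 4, 852 higher and 626 lower at day 12 and 151 at both days, and it changed no call of a gene list. Among 159 single-gene results it left 136 on their side of the threshold, brought 18 past it and took 5 off it. The self-test on simulated data did not recover more genes with the block, but its arrays held no effect of replicate number or pair. It could therefore not show a gain from the block, and why the real counts rose was not tested.

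For other alternatives the cause was not tested either. Array weights gave 2 genes lower at day 4 and 668 higher and 308 lower at day 12. The 8 cell means gave 4 lower at day 4, 235 higher and 65 lower at day 12, and 58 over time. Centring on the housekeeping list gave 59 and 3 at day 4, 251 and 103 at day 12, and 56 at both days. The floor gave 164 and 24 at day 4, 155 at both days and 329 over time. The offset gave 17 lower at day 4 and 312 over time, and the cyclic loess 16 lower at day 4. Over time, leaving dim genes out gave 344, the mean of probe sets 88, and trend and robust moderation 352.

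Lists past the threshold numbered 5 at day 4 and 7 at day 12. At day 4 there were 3 with the mean of probe sets, with every probe set, in clone 15 alone, at an adjusted p under 0.01, with an estimated correlation, and in arrays numbered 2 alone. At day 12 there were 4 in clone 15 alone, at an adjusted p under 0.01 and in arrays numbered 1 alone, and 3 with an estimated correlation. Of 44 list results, fry brought 2 past the threshold and took 2 off it. Those gained were imprinted genes at day 4 (fry adjusted p = 0.0219) and PRC2 components at day 12 (fry adjusted p = 0.00675). Every probe set brought 3 past it and took 2 off it, and leaving dim genes out brought 2 past it and took 1 off it. The stricter threshold gives fewer by construction, and for the rest the cause was not tested.

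The test of the day difference gave 0 genes by limma (832 at an unadjusted p under 0.05). It gave 1 with the mean of probe sets (Spic, 2.87 ± 0.35, limma adjusted p = 0.0347), 1 with 8 cell means (Lcn9, 3.49 ± 0.30, 0.0109) and 1 with the block of 8 pairs (Tmlhe, 2.37 ± 0.17, 0.0341), each named after its value was seen, and the cause was not tested. The correlation between clones across genes, 0.163 at day 4 and 0.255 at day 12, was 0.381 and 0.526 without dim genes, 0.399 and 0.554 with the offset, and 0.359 and 0.5203 with the floor. It was 0.1198 and 0.1996 over every probe set, 0.161 at day 4 with the cyclic loess, 0.0897 and 0.141 in arrays numbered 1, and 0.0870 and 0.137 in arrays numbered 2, and the cause was not tested.

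Without each array in turn, the counts ranged from 62 to 102 and from 1 to 11 at day 4, from 202 to 380 and from 83 to 159 at day 12, from 57 to 88 at both days and from 94 to 167 over time. Lists ranged from 3 to 6 at day 4, with 3 without KO day 4 clone 10 replicate 1, KO day 4 clone 15 replicate 1 or control day 4 clone 15 replicate 2, and from 5 to 8 at day 12. The day difference stayed at 0. Among the 3 members with the largest change of each list, 11 genes passed at day 4 and 25 at day 12. Of these, 7 and 18 stayed past the threshold in every such fit, while Foxa1 at day 12 lost its call in 7 of 16. The clone difference ranged from 0 to 2 at day 4, with 1 without control day 4 clone 15 replicate 1, KO day 4 clone 15 replicate 1 or KO day 4 clone 10 replicate 2 and 2 without control day 12 clone 15 replicate 1 or clone 15 replicate 2. At day 12 it ranged from 0 to 1, with 1 without control day 12 clone 15 replicate 2. The correlation between clones ranged from 0.126 to 0.163 and from 0.187 to 0.255. A clone and group left with 1 array is assumed to vary like the others. Signal over background limits dim genes, whose SD between arrays was 1.19 on the log2 scale below a mean of 5.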

Other observations

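The list tests over time in untreated cells, and the comparison of primitive endoderm genes with other lineages and with feeder collagens, were chosen only after the results were seen; the primitive endoderm term was added after seeing the data, and its bound and that of the neighbour count were set before their results.

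Primitive endoderm genes rose in untreated cells between day 4 and day 12. Of 35 measured members 19 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.87 (camera adjusted p = 1.1e-40, 0.00615 with an estimated correlation). The basement membrane collagen gene Col4a1 went from 598 to 5481 (3.34 ± 0.47), and the lineage regulators Gata6 from 82.9 to 382 (2.19 ± 0.24) and Sox17 from 85.3 to 477 (2.67 ± 0.56). A lower share of undifferentiated cells would raise every other lineage alike, but the median primitive endoderm member exceeded the median mesoderm or neural member by 1.96 (1.90 over 34 genes against -0.07 over 51, two-sided permutation p = 1e-05, the smallest these permutations can give). The permutations treat genes as independent, so this p does not measure the spread between arrays. Some mesoderm members, such as Gsc and Wnt3, had means under 28.3 at both days, which limits the rise they could show. Feeder fibroblasts would bring their collagens, whose largest change was 0.79 ± 0.50, in Col1a1, with 0.33 ± 0.27 in Col1a2 and 0.13 ± 0.21 in Col3a1. A growing share of primitive endoderm-like cells, or a change within the ES cells, is consistent with these values as a hypothesis, and the arrays cannot separate them.

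At day 12 the primitive endoderm list mean was higher in KO cells in 3 of 4 pairs (0.53 ± 0.42, SD, n = 4, from -0.07 to 0.88), and the list did not pass camera with an estimated correlation (adjusted p = 0.241). A larger share of primitive endoderm-like cells was still tested as the source of the other differences. With the primitive endoderm mean of each array as a term, 279 of the 562 genes stayed past the limma threshold. Of the 283 that did not, all kept their sign, their median absolute log2 fold change went from 0.84 to 0.75 and their median standard error from 0.18 to 0.22, so both a smaller effect and a larger error ended calls. The fit with the term found 496 genes, 217 of them not found before. Within a clone and group the primitive endoderm mean was mostly higher in replicate 1, as in KO day 12 clone 10 (9.97 against 9.27). Control day 12 clone 10 was the exception (9.21 against 9.34). The term can therefore take up differences between replicate numbers as well, and the 2 were not separated. The effects shrank little, so such a share stays open as a source of part of the day 12 differences and is not shown. Of the 2-cell and germline genes 25 of 37 stayed at day 12 and 18 of 18 at day 4, where 107 of 113 genes stayed. The 12 lost kept a median log2 fold change of 2.02 (1.95 before) while their median standard error went from 0.41 to 0.54.

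Other lists shifted over time in untreated cells. Of the trophectoderm list 4 rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 5.4e-04, 0.0171 with an estimated correlation), and the keratin gene Krt8 went from 439.7 to 2098 (2.24 ± 0.23). The amino acid stress response list had 1 riser, Slc3a2 (0.70 ± 0.09), 3 adjusted over the list alone, and a camera adjusted p of 0.00243 (0.0353 with an estimated correlation). The feeder fibroblast list had 1 riser, 5 adjusted over the list alone, and a camera adjusted p of 3.6e-04, but adjusted p = 0.0870 with an estimated correlation.

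Genes higher at day 12 in KO cells often lie side by side in the mouse genome, assembly GRCm38.p6. Shared local regulation or shared probes of neighbours would place them so. Among the 399 genes 27 neighbouring pairs were found, against a median of 9 and a maximum of 22 in 10000 random lists of that size (one-sided permutation p = 1e-04, the smallest they can give). At day 4 5 pairs were found among 103 genes (p = 5e-04 by the same permutation), and among genes lower at day 12 4 pairs (permutation p = 0.058). The pairs include AF067061, Gm20767, Tcstv1 and Tcstv3 in 1 cluster, Rhox6, Rhox9 and Rhox13 in another, and Tex19.1 beside Tex19.2. Either source may hold, and probe sequences were not compared.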
